A study of Arabidopsis thaliana with 9 samples.

How the data were processed

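Gene expression was measured with Affymetrix ATH1 arrays, on which each gene is read by 1 or more probe sets, in T87 cells of Arabidopsis thaliana. Per the labels, the 9 arrays are 3 biological replicates each of intact cells, osmotic cells and protoplasts, so p-values measure the spread between those replicates. Per the labels' protocols, total RNA was labelled with biotin from its 3-prime end and 750 ng of RNA was used. The deposited values are intensities on a linear scale, 1 per probe set and array. The values themselves show that each array was scaled by 1 factor to a trimmed mean of 500 over all probe sets, leaving out the top and bottom 2%, and that the arrays were not made equal in distribution. The software that summarised the probes is not given in the sources used here, and no detection calls were used here, so dim probe sets could not be told from background.

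Probe sets were named from a table of the array's annotation, which can be old. Of 22746 probe sets other than 64 controls, 13513 had 1 gene symbol, most often a locus code, 503 had several and 8730 were not named by it. Loci of 13286 genes were matched in a gene table of the assembly TAIR10.1, used for names, membership of gene lists and organelle genes only. A gene with more than 1 one-gene probe set, as 146 of 13356 had, was read from its brightest.

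Values were analysed as log2(intensity + 16), which understates the fold changes of dim genes. All 9 arrays entered 1 linear model in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with empirical Bayes variances, and p-values were adjusted by Benjamini-Hochberg within each of the 3 comparisons. A gene was called at an adjusted p under 0.05, and counts with at least a 2-fold change are given beside it. Names and figures were handled with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. On simulated arrays with 200 of 13356 genes changed, the model called 31.8% of 2-fold and 77% of 4-fold changes in osmotic against intact cells, 32.6% and 77.6% in protoplasts against intact cells, and 0.0365% and 0.038% of unchanged genes. These shares hold for that setting only. In the data, 7.34% and 45.0% of genes were called in these comparisons, which moves the threshold. The simulated changes were added after the log2 step, so dim genes lost none of their fold change.

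Gene lists, comparisons, tests, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were, per comparison, the 8 largest rises and 8 largest falls among called genes with a symbol other than the locus code and no overlap between arrays, up to 2 rises and 2 falls per list or the 2 lowest p where no member was called, the 5 largest rises and falls set apart in protoplasts, and up to 5 genes called in opposite directions. Other list members, among them STZ, PRL, XTH20, BIK1, WRKY53, COR15A, COR47 in protoplasts, GSTU21 and GSTU28, were named after their values were seen. RD29A, NCED3, P5CS1, CESA1, CESA3, CESA6, WRKY33 and JAZ1, also fixed for naming, had no one-gene probe set by the annotation and were not analysed here.

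Lists with at least 5 measured members were tested with limma's camera, at an inter-gene correlation of 0.01, with an estimated correlation and limma's fry as alternatives, and adjusted over 9 lists per comparison. Smaller lists are given as their members' values. The lists of callose synthases, antioxidant enzymes, core hypoxia genes and aquaporins, and those of both organelle genomes by locus code, had 0 measured members. After the annotation was seen and before any test, 47 lists were added, 45 families of symbols with a common stem and both organelle genomes, adjusted over themselves.

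The alternatives were a replicate block, fits to only the groups compared, other variance priors, array weights, 3 other scalings (quantile normalization, median centring, centring on hybridisation controls), leaving out the dimmest 40% of genes, the mean of probe sets or every probe set, pseudocounts of 1 and 64, an adjusted p under 0.01, and leaving out each array. After the third arrays were seen to deviate together, fits to replicates 1 and 2 alone and with a term for the third arrays were added. Control probe sets were compared by exact permutation tests, two-sided. The correlation and covariance of both responses were set against 20 simulations of unchanged groups with the same intact arrays.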

Results

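The data are 9 Affymetrix ATH1 arrays of the Arabidopsis T87 suspension cell line, a culture of undifferentiated cells, in 3 groups of 3 biological replicates. Intact cells were taken from 4-day-old cultures. Osmotic cells had spent 3 h in medium with 0.4 M mannitol, an osmolyte that draws water out of the cell. Protoplasts had lost their walls to cellulase and pectolyase in 1.5 h of digestion in 0.35 M mannitol, had been washed 3 times, and had then spent the same 3 h in medium with 0.4 M mannitol. Median intensities were 154 ± 2.2 in intact, 155 ± 9.42 in osmotic and 123 ± 7.56 in protoplast arrays (SD, n = 3). Over 13356 genes, the first principal component held 70.2% of the variance and separated protoplasts from the other groups, and the second held 10.2%. The number of arrays limits the precision of every value. Of these genes, 1557 had a symbol other than their locus code, and the largest rises and falls named below are the largest among called genes with such a symbol and no overlap between arrays, so genes known by locus code alone can have larger changes.

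The osmotic cells were compared with intact cells to ask what mannitol medium does to gene expression when the wall stays in place. The labels give no mock change of medium for the intact cells. Mannitol thus cannot be told apart here from the change of medium, the handling or the time in it, and "in mannitol" below stands for these together. The dehydrin gene LTI30 (AT3G50970), which encodes a protein that accumulates in water-stressed cells, went from an intensity of 278 ± 24.2 to 7779 ± 2385 (SD, n = 3). This was a log2 change of 4.68 ± 0.25 (SE, limma adjusted p = 3.1e-05). Another dehydrin gene, COR47 (AT1G20440), rose by 4.63 ± 0.88 (limma adjusted p = 0.016), and ZCF37 (AT1G59590) by 4.48 ± 0.41 (limma adjusted p = 5.5e-04). The next largest rises among genes with symbols were those of SIS with 3.57, the metallothionein gene MT1C with 3.26, the Aux/IAA gene IAA30 with 3.21, the autophagy gene ATG8H with 2.75 and the U-box ubiquitin ligase gene PUB23 with 2.75. Values are on the log2 scale. Falls were smaller. EXO (AT4G08950), a brassinosteroid-responsive growth gene, changed by -2.52 ± 0.25 (limma adjusted p = 7.3e-04). The actin-binding protein gene NET1A changed by -1.88, SKU5, which encodes a membrane-anchored protein of directional root growth, by -1.74, and the receptor kinase gene MOL1 by -1.74. PSY1R with -1.62, UBP21 with -1.57, the jasmonate transcription factor gene MYC4 with -1.55 and the DNA topoisomerase gene TOPII with -1.54 completed the 8 largest falls among genes with symbols. Over all genes, 37 rose and 3 fell at least 8-fold. With pseudocounts of 1 and 64 in place of 16, ZCF37 had 5.63 and 3.27 and SIS 4.47 and 2.45. In all, 478 genes were higher and 502 lower (limma adjusted p under 0.05), 7.34% of all genes tested, and 339 and 281 of them differed at least 2-fold.

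The list tests rest on few of the genes written for them, 6 of 40 for the osmotic and abscisic acid list and 6 of 31 for pattern-triggered immunity. The latter were WRKY22, WRKY53, BIK1 and the U-box ubiquitin ligase genes PUB22, PUB23 and PUB24. Others, such as FRK1, WRKY33 and FLS2, had no one-gene probe set. Among the lists fixed in advance, 3 of the 6 measured osmotic and abscisic acid genes rose and none fell, with a median log2 change of 1.30 (limma's camera adjusted p = 0.00245, and adjusted p = 0.136 with an estimated correlation). The same 3 members, LTI30, COR47 and the zinc finger gene STZ with 1.28 ± 0.31, were called when adjusted over the list alone, while COR15A had 1.32 ± 0.59 and did not pass (limma adjusted p = 0.223). Of the 6 genes of pattern-triggered immunity, 4 rose, with a median of 1.90 (limma's camera adjusted p = 1.3e-04, and adjusted p = 0.174 with an estimated correlation). 5 rose and 0 fell adjusted over the list alone. PUB23 rose by 2.75 ± 0.40 and the transcription factor gene WRKY22 by 2.52 ± 0.29. Of the 7 WRKY genes, which share WRKY22 and WRKY53 with the immunity list, 3 rose (limma's camera adjusted p = 0.00245, and adjusted p = 0.246 with an estimated correlation). 4 rose and 0 fell adjusted over the list alone, with WRKY6 at 2.16 ± 0.36. Of the 11 tau class glutathione transferase genes, 4 rose (limma's camera adjusted p = 0.00245, and adjusted p = 0.136 with an estimated correlation). 4 rose and 1 fell adjusted over the list alone. GSTU25 rose by 2.56 ± 0.23 and GSTU22 by 2.19 ± 0.29, beside GSTU28 and GSTU21, and PUB22 and WRKY53 completed the immunity calls. Of the 6 genes of DNA replication and histones, 1 fell, the replication licensing gene PRL with -0.86 ± 0.16, and the median was -0.56 (limma's camera adjusted p = 0.00245, and adjusted p = 0.136 with an estimated correlation). Adjusted over the list alone, 4 of them fell.

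None of the tested lists of wall genes passed limma's camera in mannitol, though single members were called. With limma's fry, which tests a list against no change, the xyloglucan endotransglucosylase list had adjusted p = 0.0403. Of the 10 xyloglucan endotransglucosylase genes, which cut and rejoin wall xyloglucan, 3 rose, XTH18 by 2.36 ± 0.29, XTH19 by 1.29 ± 0.29 and XTH20 by 0.94 ± 0.24, but the median was -0.01 against a mean of 0.24 and the list did not pass (limma's camera adjusted p = 0.542, and adjusted p = 0.616 with an estimated correlation). 3 rose and 0 fell adjusted over the list alone. Of the 19 expansin genes, 1 fell, EXPB3 with -1.09 ± 0.26, while the median was 0.06 and the mean below 0 (limma's camera adjusted p = 0.627, and adjusted p = 0.762 with an estimated correlation). 0 rose and 1 fell adjusted over the list alone. None of the 7 class III peroxidase genes was called (limma's camera adjusted p = 0.627, and adjusted p = 0.714 with an estimated correlation), nor was one adjusted over the list alone, and PRX52 had 1.20 ± 0.66. None of the 7 nuclear photosynthesis genes was called (limma's camera adjusted p = 0.354, and adjusted p = 0.616 with an estimated correlation), nor was one adjusted over the list alone, with LHCB4.2 at 0.82 ± 0.29 and PSAE-1 at 0.33 ± 0.19. Among lists too short to test, COB, which guides cellulose deposition, fell by 0.98 (limma adjusted p = 0.0175). The wall receptor kinase gene THE1 changed by -1.12 ± 0.21 (limma adjusted p = 0.0139). The cinnamoyl-CoA reductase gene CCR2 of monolignol synthesis rose by 2.57 ± 0.42 (limma adjusted p = 0.00795). The endoplasmic reticulum stress factor gene BZIP60 rose by 1.92 ± 0.17 (limma adjusted p = 4.4e-04). The Aurora kinase genes AUR1 and AUR2 of mitosis changed by -0.68 ± 0.17 and -1.11 ± 0.19 (limma adjusted p = 0.045 and 0.00918). IVD of the carbon starvation list rose by 0.77 ± 0.17 (limma adjusted p = 0.0253).

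Which genes passed in mannitol depended on single arrays: the 478 rises became 238, 258 and 277 without intact replicate 1, 2 or 3, and 260 and 202 without osmotic replicate 1 or 2, and the 502 falls became 184, 185, 221, 241 and 158. The 2-fold counts of 339 and 281 became 195 and 147 without osmotic replicate 2, and the 281 falls became 162 and 169 without intact replicate 1 or 2. The counts of rises and falls also moved to 1189 and 1193 with array weights and to 300 and 214 with a pseudocount of 1. Among the genes named for mannitol, those that lost their call without at least 1 array had a highest limma adjusted p without intact replicate 1 for COR47 at 0.0653, IVD at 0.0916 and GSTU21 at 0.154, without intact replicate 2 for XTH20 at 0.138, EXPB3 at 0.131 and COB at 0.0692, without osmotic replicate 1 for AUR1 at 0.142, and without osmotic replicate 2 for MYC4 at 0.139, STZ at 0.126, PUB22 at 0.15, WRKY53 at 0.145, XTH19 at 0.116, THE1 at 0.0616, PRL at 0.0592 and GSTU28 at 0.104.

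**Figure D1:**
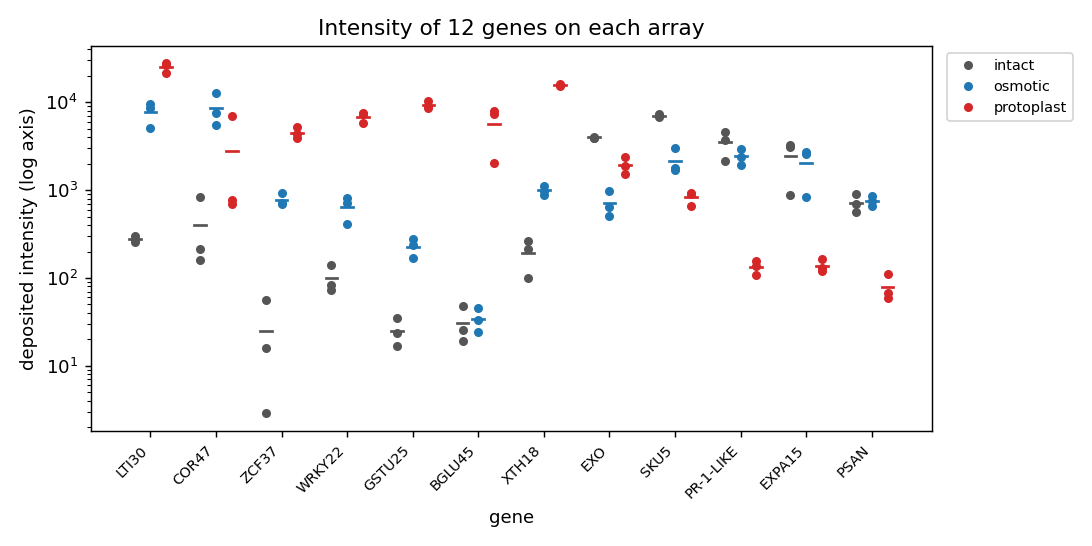
Deposited intensity, on a log axis, of 12 genes on each of the 9 arrays. Points are arrays, bars are means of 3 arrays, and LTI30 lies at 278, 7779 and 25217 in intact, osmotic and protoplast cells.

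Protoplasts were compared with intact cells, again without a mock change of medium, to ask what wall removal, washing and mannitol medium do together. GSTU25 (AT1G17180), a glutathione transferase gene, went from 25.1 ± 9.08 to 9367 ± 822 (SD, n = 3). This was a log2 change of 7.85 ± 0.23 (limma adjusted p = 1.7e-07). The glycosyltransferase genes UGT73B4, UGT73D1, GT72B1 and UGT73B5 rose by 7.49, 6.66, 6.57 and 6.57, AR781 by 6.95, and BGLU45, a beta-glucosidase gene of the monolignol glucoside group, by 6.75 on the log2 scale. Their standard errors lay between 0.34 and 0.53. ZCF37 went from 25.1 ± 27.8 to 4520.1 ± 660.2 (SD, n = 3). Among the falls, PR-1-LIKE (AT2G19990) changed by -4.50 ± 0.29 (limma adjusted p = 3.8e-06). NET3C changed by -3.88, the subtilisin-like protease gene ARA12 by -3.82, the expansin genes EXPA15 and EXPA4 by -3.78 and -3.35, IQD24 by -3.64, the glycosyl hydrolase gene GH9B13 by -3.62 and MOL1 by -3.42. For dim genes these sizes and their order depend on the pseudocount: with 1 and with 64 in place of 16, GSTU25 had 8.54 and 6.73, UGT73B4 9.47 and 5.76, and NET3C -5.45 and -2.45. In all, 2108 genes were higher and 3902 lower (limma adjusted p under 0.05), with 1564 and 2775 at least 2-fold apart.

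All 6 measured genes of pattern-triggered immunity rose in protoplasts, over all genes and adjusted over the list alone, with a median log2 change of 4.29 (limma's camera adjusted p = 4.4e-05, and adjusted p = 0.153 with an estimated correlation). WRKY22 rose by 5.94 ± 0.29 and PUB23 by 5.37 ± 0.40, while BIK1, a receptor-like cytoplasmic kinase gene, rose by 3.88 ± 0.37. Of the 7 WRKY genes, 4 rose (limma's camera adjusted p = 0.0483, and adjusted p = 0.344 with an estimated correlation). 4 rose and 1 fell adjusted over the list alone. Of the 11 tau class glutathione transferase genes, 4 rose (limma's camera adjusted p = 0.00777, and adjusted p = 0.153 with an estimated correlation). 4 rose and 0 fell adjusted over the list alone, with GSTU22 at 4.19 ± 0.29. Of the 6 osmotic and abscisic acid genes, 2 rose, LTI30 by 6.42 ± 0.25 and STZ by 4.73 ± 0.31 (limma's camera adjusted p = 0.0483, and adjusted p = 0.153 with an estimated correlation). 2 rose and 0 fell adjusted over the list alone. COR47 had 2.25 ± 0.88 and did not pass (limma adjusted p = 0.0643). Among lists too short to test, OPCL1 of jasmonate synthesis rose by 3.29 ± 0.49, the immune gene SAG101 of the salicylate list by 2.52 ± 0.20, EIN3 of ethylene signalling by 0.77 ± 0.19 and BZIP60 by 3.97 ± 0.17, and the chaperone gene CRT1b changed by -1.37 ± 0.17 (limma adjusted p at most 0.00878). The jasmonate, salicylate and ethylene lists had 1 measured member each, and in mannitol OPCL1, SAG101 and EIN3 had 1.10 ± 0.49, 0.25 ± 0.20 and 0.18 ± 0.19 and did not pass. Without 1 array the list call of the osmotic genes ended, with limma's camera adjusted p = 0.0512 without intact replicate 1, 0.0518 without intact replicate 3, 0.0566 without osmotic replicate 1, 0.0703 without osmotic replicate 3 and 0.0893 without protoplast replicate 3. The list call of the WRKY genes ended with limma's camera adjusted p = 0.0512 without intact replicate 1, 0.08 without intact replicate 2 and 0.113 without protoplast replicate 3. Other alternatives also ended these list calls: for the osmotic genes limma's camera adjusted p was 0.0664 with a fit to these groups only, 0.0592 with quantile normalization, 0.0761 with median centring, 0.058 with a pseudocount of 1, 0.121 with replicates 1 and 2 alone and 0.0751 with a term for the third arrays, and for the WRKY genes 0.0567 with a pseudocount of 1, 0.0616 with a pseudocount of 64 and 0.0771 with a term for the third arrays. The replicate number as a block ended both list calls as well, with values given under the processing below. Calls of members lost without 1 array had a highest limma adjusted p without intact replicate 1 for WRKY53 at 0.0545, and without protoplast replicate 2 for GSTU28 at 0.0503.

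Wall genes went both ways in protoplasts. Of the 10 xyloglucan endotransglucosylase genes, 4 rose, with XTH19 at 6.37 ± 0.29 and XTH18 at 6.33 ± 0.29 (limma's camera adjusted p = 0.0049, and adjusted p = 0.129 with an estimated correlation). 4 rose and 0 fell adjusted over the list alone. Of the 19 expansin genes, 2 rose and 5 fell, with a median of -0.01 and a mean of -0.60, EXPA15 at -3.78 ± 0.56 and EXLA3 at 1.13 ± 0.25 (limma's camera adjusted p = 0.816, and adjusted p = 0.892 with an estimated correlation). 1 rose and 5 fell adjusted over the list alone. Of the 7 class III peroxidase genes, 3 rose and 1 fell, with Prx37 at 4.73 ± 0.63, PRX52 at 4.59 ± 0.66 and PRXR1 at -3.35 ± 0.61 (limma's camera adjusted p = 0.127, and adjusted p = 0.197 with an estimated correlation). 3 rose and 1 fell adjusted over the list alone. CCR2 rose by 6.21 ± 0.42 and HCT, also of monolignol synthesis, by 3.51 ± 0.32. CSLC04, a synthase gene of the xyloglucan backbone, rose by 2.73 ± 0.20 and the pectin-modifying genes ATPMEPCRB, AT4G02300 and PME61 by 1.62 ± 0.25, 1.30 ± 0.26 and 0.76 ± 0.22. COB changed by -2.30 ± 0.19 and THE1 by -1.87 ± 0.21, while the related receptor kinase gene FER rose by 0.63 ± 0.17 (limma adjusted p at most 0.0173 for these 9 genes). Calls lost without 1 array had a highest limma adjusted p without intact replicate 3 for PME61 at 0.0644, and without protoplast replicate 1 for EXPB5 at 0.151.

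All 6 genes of DNA replication and histones fell, over all genes and adjusted over the list alone, with a median of -1.14 (limma's camera adjusted p = 0.00536, and adjusted p = 0.153 with an estimated correlation). The centromeric histone gene HTR12 changed by -2.16 ± 0.25 and PRL by -1.97 ± 0.16. AUR2 and AUR1 changed by -2.12 ± 0.19 and -1.33 ± 0.17. All 7 nuclear photosynthesis genes fell, over all genes and adjusted over the list alone, with a median of -1.12 (limma's camera adjusted p = 0.00552, and adjusted p = 0.153 with an estimated correlation). PSAN, a photosystem I subunit gene, changed by -2.96 ± 0.25, and LHCB4.3 by -1.71 ± 0.36. MCCB and MCCA of the carbon starvation list, enzymes of leucine breakdown, changed by -2.66 ± 0.33 and -1.14 ± 0.27, and the ribosomal protein gene AT1G77750 by -1.39 ± 0.22 (limma adjusted p = 1.3e-04, 0.00659 and 6.8e-04). In mannitol AT1G77750 had 0.07 ± 0.22 and did not pass. The heat shock gene ATHSP22.0 varied between arrays and did not pass in mannitol, with 3.69 ± 1.27, nor in protoplasts, with 2.27 ± 1.27. Among markers of other cell types, the root hair genes EXPA7 and EXPA18 had mean intensities of 16.5 and 27.2 in protoplasts and differed from intact cells by -0.01 ± 0.37 and -0.24 ± 0.34, and the secondary wall gene GUT2 by -0.08 ± 0.15. PRP39, which its symbol alone placed in the list of hydroxyproline-rich wall proteins, had -0.34 ± 0.16, and none of these 4 genes passed in any of the 3 comparisons. Calls lost without 1 array had a highest limma adjusted p without protoplast replicate 2 for HTB1 at 0.0589 and LHCB4.2 at 0.0611.

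The balance of rises and falls in protoplasts depended on how arrays were scaled: 64.9% of the called genes were lower as deposited, 51.1% after centring each array on its median, 60.5% after quantile normalization and 72.7% after centring on the hybridisation controls. The median change of all genes was -0.10 as deposited, 0.07 with median centring and -0.24 with hybridisation controls, and relative to these shifts 5 of 6 replication and histone genes and 4 of 7 photosynthesis genes still fell with median centring.

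**Figure D2:**
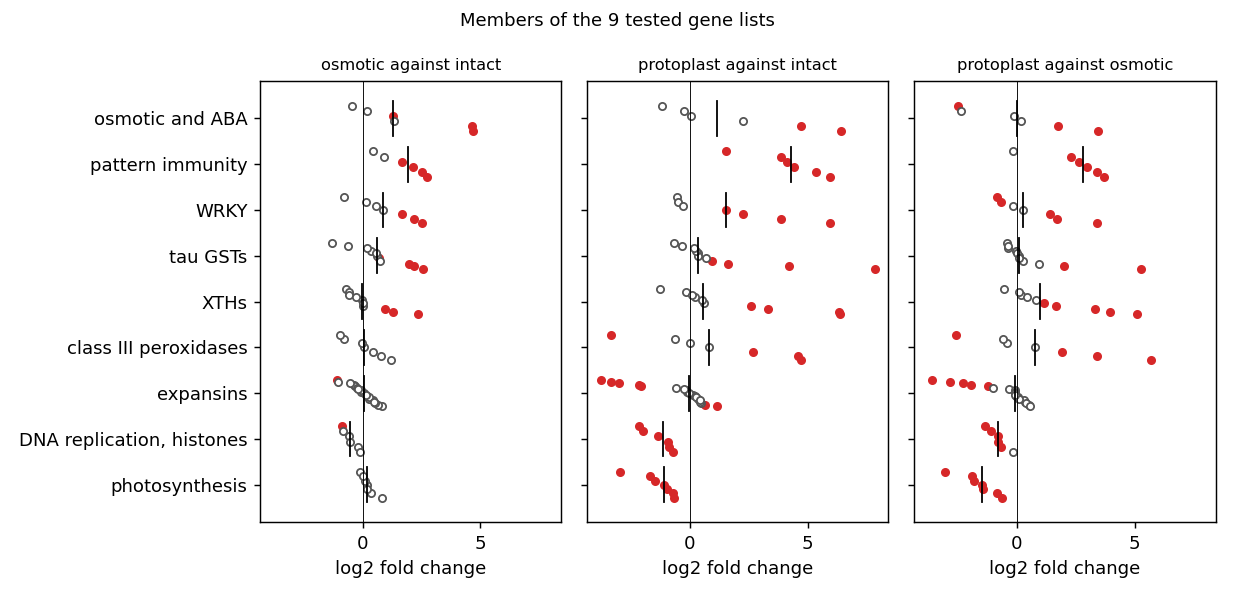
Log2 fold change of every measured member of the 9 tested gene lists in the 3 comparisons, on a shared axis. Filled red points passed limma's adjusted p under 0.05, open points did not, and black bars mark list medians, which for pattern-triggered immunity were 1.90, 4.29 and 2.80 from left to right.

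Protoplasts were compared with osmotic cells, which had the same final mannitol molarity and time, to ask what differs with wall digestion and its washes. Protoplasts had also spent the 1.5 h of digestion in 0.35 M mannitol, so this comparison does not separate digestion from longer exposure to mannitol. BGLU45 and BGLU46, beta-glucosidase genes, went from 34.5 ± 10.7 and 22.3 ± 15.9 in osmotic cells to 5733 ± 3233 and 3359 ± 2579 in protoplasts (SD, n = 3). Their log2 changes were 6.62 ± 0.48 and 5.90 ± 0.85 (limma adjusted p = 2.2e-05 and 5.6e-04), but against such dim levels the size of a change depends on the pseudocount, and with 64 in place of 16 BGLU45 and BGLU46 had 5.66 and 4.71. UGT73D1 rose by 5.81, Prx37 by 5.70, GT72B1 by 5.68, UGT73B4 by 5.45, AR781 by 5.34 and the glutaredoxin gene GRX480 by 5.31. The largest falls among genes with symbols were those of PR-1-LIKE with -4.02 ± 0.29 and EXPA15 with -3.58 ± 0.56 (limma adjusted p = 2.2e-05 and 8.5e-04). Next came the linker histone gene HIS1-3 with -3.38, the thylakoid translocase gene SECE1 with -3.36, the auxin-conjugating enzyme gene GH3.17 with -3.29, TET2 with -3.22, GH9B8 with -3.13 and PSAN with -3.04. With pseudocounts of 1 and 64 GH9B8 had -4.73 and -1.79. In all, 1772 genes were higher and 3435 lower (limma adjusted p under 0.05), with 1306 and 2192 at least 2-fold apart.

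Of the 6 immunity genes, 5 rose further above their level in mannitol, with PUB24 at 3.71 ± 0.40 and WRKY53 at -0.14 ± 0.43, which did not pass (limma's camera adjusted p = 4.3e-04, and adjusted p = 0.233 with an estimated correlation). 5 rose and 0 fell adjusted over the list alone. Of the 10 xyloglucan endotransglucosylase genes, 5 rose, with XTH19 at 5.09 ± 0.29 and XTH18 at 3.97 ± 0.29 (limma's camera adjusted p = 4.3e-04, and adjusted p = 0.0488 with an estimated correlation). 5 rose and 0 fell adjusted over the list alone. All 7 photosynthesis genes fell as deposited, with quantile normalization and with hybridisation controls, and 6 with median centring (limma's camera adjusted p = 8.2e-04, and adjusted p = 0.233 with an estimated correlation). 0 rose and 7 fell adjusted over the list alone. Of the 6 replication and histone genes, 5 fell (limma's camera adjusted p = 0.0296, and adjusted p = 0.233 with an estimated correlation). 0 rose and 5 fell adjusted over the list alone. Of the 6 osmotic and abscisic acid genes, 2 rose and 1 fell, with STZ at 3.45 ± 0.31 and COR15A at -2.48 ± 0.59 (limma's camera adjusted p = 0.308, and adjusted p = 0.44 with an estimated correlation). 2 rose and 2 fell adjusted over the list alone. The 19 expansins, with none higher and 5 lower (limma's camera adjusted p = 0.461, and adjusted p = 0.67 with an estimated correlation), the 7 peroxidases, with 3 higher and 1 lower (limma's camera adjusted p = 0.207, and adjusted p = 0.298 with an estimated correlation), the 7 WRKY genes, with 3 higher and 2 lower (limma's camera adjusted p = 0.224, and adjusted p = 0.555 with an estimated correlation), and the 11 glutathione transferases, with 2 higher (limma's camera adjusted p = 0.104, and adjusted p = 0.298 with an estimated correlation), did not pass as lists. Their counts adjusted over the list alone were the same. The falls of replication genes were relative to the scaling: 2 of 6 were called with median centring (limma's camera adjusted p = 0.0788, with 0.0961 when the dimmest 40% of genes were left out and 0.0731 with replicates 1 and 2 alone), and with 1 array left out the list had limma's camera adjusted p = 0.0551 (without osmotic replicate 3). With 1 array left out the glutathione transferases passed, with limma's camera adjusted p = 0.0197 (without osmotic replicate 1). Calls of members lost without 1 array had a highest limma adjusted p without osmotic replicate 2 for LHCB4.1 at 0.0566, without protoplast replicate 1 for WRKY20 at 0.121 and EXLA1 at 0.128, and without protoplast replicate 3 for WRKY47 at 0.0914. The share of lower genes among those called was 66.0% as deposited, 48.5% with median centring, 58.4% with quantile normalization and 75.6% with hybridisation controls.

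Genes set apart in protoplasts, at least 2-fold from both other groups in one direction, numbered 1138 higher and 1889 lower as deposited, but 1141 lower with median centring. By the smaller of both changes, among genes with symbols, BGLU45, BGLU46, UGT73D1, GT72B1 and UGT73B4 led the rises and PR-1-LIKE, EXPA15, GH3.17, PSAN and SECE1 the falls. GT72B1 went from 102 ± 31.8 in intact and 199 ± 22.7 in osmotic cells to 11895 ± 5185 in protoplasts (SD, n = 3), and PR-1-LIKE from 3501 ± 1246 and 2421 ± 492 to 134 ± 24.4. Only 20 genes were called in opposite directions against intact cells, 13 higher in mannitol and lower in protoplasts and 7 the reverse. The clearest was AT4G35720, with 2.13 ± 0.31 in mannitol and -2.29 ± 0.31 in protoplasts (limma adjusted p = 0.0051 and 2.6e-04). It was followed by AT1G61400 with -1.53 and 1.17, AT1G67820 with 1.17 and -1.36, AT1G49200 with 1.15 and -1.21, and AT5G11460 with 1.04 and -1.63. These counts of 13 and 7 ran from 2 to 49 and from 1 to 24 when single arrays were left out, with 2 and 1 without intact replicate 1 or 2, 2 and 3 without osmotic replicate 2, and 49 and 24 without protoplast replicate 3. Calls in mannitol lost without 1 array had a highest limma adjusted p without intact replicate 1 for AT1G61400 at 0.138 and AT1G49200 at 0.0907, without intact replicate 3 for AT1G67820 at 0.087, and without osmotic replicate 2 for AT5G11460 at 0.142, while in protoplasts the highest was without protoplast replicate 1 for AT1G61400 at 0.102.

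The mannitol and protoplast responses were then set side by side. Of the genes called in mannitol, 393 of 478 rises (82.2%) and 434 of 502 falls (86.5%) were called in the same direction in protoplasts, where independent lists of these sizes would share 75.4 and 147 genes. With at least 2-fold changes, 278 and 240 genes were shared, where independent lists would share 39.7 and 58.4. Leaving out 1 array moved the shared rises and falls to 212 and 168, 230 and 170 or 243 and 201 without intact replicate 1, 2 or 3, and to 224 and 208 or 178 and 145 without osmotic replicate 1 or 2. The 2-fold counts became 167 and 131 without osmotic replicate 2, and the 2-fold falls 145 and 149 without intact replicate 1 or 2. Across genes, which are not independent replicates, the fold changes of both comparisons correlated with r = 0.622 and a covariance of 0.510. Simulations of unchanged groups, in which both comparisons shared the simulated intact arrays, gave r = 0.501 ± 0.011 and a covariance of 0.0444 ± 0.0014 (SD, 20 simulations). Sharing a control group sets this r by itself. The simulated arrays also lacked any deviation shared between the third arrays, described below. The 3 intact arrays were too few to leave at least 2 for each comparison, so part of the excess of shared genes over independent lists may come from the shared controls. The numbers for independent lists also treat all genes, dim ones included, as equally likely to be called. Both comparisons used the same variance per gene, which favours calls of the same genes. The excess may thus be overstated, by an amount that was not tested.

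**Figure D3:**
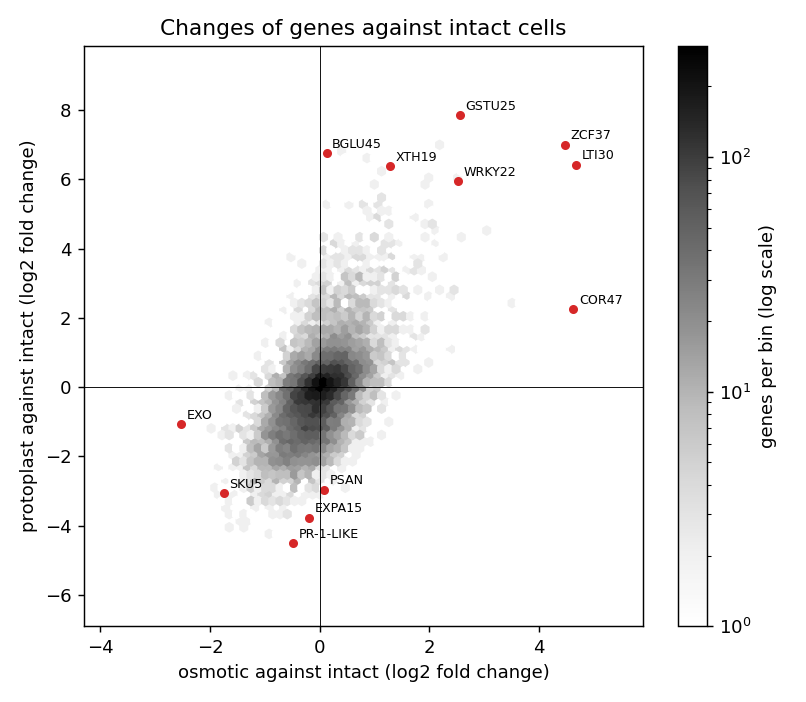
Log2 fold change of 13356 genes in mannitol (horizontal axis) and in protoplasts (vertical axis) against intact cells, with darker bins holding more genes on a log scale. Red points mark 12 named genes, among them COR47 at 4.63 and 2.25 and BGLU45 at 0.13 and 6.75.

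Control probe sets on the arrays gave signs of RNA quality. The log2 difference between 3-prime and 5-prime signal of actin was 3.79 ± 0.06, 3.01 ± 0.13 and 3.40 ± 0.11 in intact, osmotic and protoplast cells (SD, n = 3), with osmotic cells below intact cells by 0.78 and protoplasts by 0.39 (exact permutation p = 0.1 for each, the smallest that 3 against 3 allows, two-sided). For GAPDH it was 0.31 ± 0.16, 0.35 ± 0.07 and 0.58 ± 0.19 (exact permutation p = 0.2 for protoplasts against intact cells), and for ubiquitin 1.25 ± 0.31, 1.26 ± 0.04 and 1.00 ± 0.14 (exact permutation p = 0.3). The 3-prime signal of ubiquitin was higher in protoplasts than in intact cells by 1.10 on the log2 scale and that of actin lower, with -1.11 (exact permutation p = 0.1 for each), in the same directions under all 3 other scalings. GAPDH differed by 0.03 (exact permutation p = 0.8), with the sign turned by quantile normalization (-0.13) and hybridisation control centring (-0.21).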

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

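The tests on scaling, RNA integrity, the batch of the third arrays and separate cultures, and the second choice of genes and the osmotic share for the third protoplast array, were chosen only after the result was seen. Signal was found in probe sets outside the comparisons of named genes. Of 9233 probe sets with several gene symbols or none, 809 were called in osmotic against intact cells (440 higher, 369 lower), 4802 in protoplasts against intact cells (1809 higher, 2993 lower) and 4252 in protoplasts against osmotic cells (1546 higher, 2706 lower), by limma with adjustment over all 22746 probe sets. These are 8.76%, 52.0% and 46.1% of them.

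More genes were lower than higher in protoplasts against intact cells, 64.9% of those called. The lowest share under the 3 other scalings was 51.1%, with median centring, and the others were 60.5% and 72.7%, so scaling of the arrays may account for part of the excess and cannot be told apart from it. RNA integrity was read from 3 control genes, as the difference of protoplasts from intact cells in 3-prime minus 5-prime signal. It was -0.39 for actin, 0.27 for GAPDH and -0.25 for ubiquitin, with a mean of -0.124 and a standard error of 0.200 over these genes. That error does not measure the spread between arrays, and the genes differed in sign, so the mean decides nothing. A change in total RNA per cell on wall digestion was not tested.

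The third arrays of the 3 groups deviated together from their group means, with correlations across genes of 0.31, 0.15 and 0.32. Of 4 poly-A spike transcripts, which are added to RNA before labelling, 2 (Phe and Thr) lay outside the range of the other 6 arrays on the third arrays of all 3 groups. This met the written rule for a batch, which asked for at least 2 of the 4. Thr cleared the others by 0.221 on the log2 scale, but Phe by 0.00932, less than the spread between arrays (SD 0.163, n = 6). That a gap should exceed this spread was a condition outside the written rule, and by it a processing batch of the third arrays stays open. All 4 spikes had higher means on the third arrays, 8.38 against 7.89 for Dap, 6.15 against 5.83 for Lys, 6.56 against 6.14 for Phe and 7.35 against 6.88 for Thr. Separate cultures behind the third samples would give correlations above 0 as well, and the lowest, 0.146, leaves that open. With a term for the third arrays, 761 genes were higher and 845 lower in osmotic against intact cells (limma adjusted p under 0.05).

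Changes were smaller on the third protoplast array than on the others. Among genes picked on the first array, rises fell short on the third against the second by a median of 0.506 on the log2 scale (95% of resamples of genes 0.392 to 0.637) and falls by 0.346 (0.297 to 0.394), and genes picked on the second gave 0.53 (0.402 to 0.633) and 0.534 (0.492 to 0.577) against the first. Undigested cells alone, at the share of intact or osmotic RNA given by the falls, would give at most 0.146 and 0.199 for rises, below these ranges, and one scaling factor would not make both rises and falls smaller. For this 1 array these values argue against either as the whole cause, within limits. Both acting together were not tested. Genes are not independent replicates, so the ranges do not measure the spread between arrays. The first and second protoplast arrays also correlated more with each other (r = 0.982) than with the third (0.958 and 0.955). A pick on the first or second may thus favour the other. What the third arrays of all groups share, a batch or separate cultures, stays open, and no biological explanation was tested.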

How the results depend on the processing

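The fits to replicates 1 and 2 and with a batch term were chosen only after the result was seen. No call of a list fixed in advance or of a single gene reversed, but with median centring more genes were higher (2510) than lower (2367) in protoplast v osmotic. In osmotic v intact, with 478 higher and 502 lower, more were higher with hybridisation controls (352 and 334), pseudocount 1 (300 and 214), every probe set (944 and 892) and replicates 1 and 2 alone (839 and 628). The same held without any 1 intact or osmotic array and, barely, without protoplast replicate 2 (376 and 375). Counts and list tests not listed stayed on their side of the threshold or within 1.5 times. Over all alternatives, 761 calls of single genes from the lists or named in the text were lost, 206 were gained and 9135 were made in both fits. For changed results the cause was not tested, except for the larger number of tests with every probe set, the stricter threshold and the fewer arrays left. Fewer arrays do not account for counts that rose, such as 622 higher and 708 lower in osmotic v intact without protoplast replicate 3. Signal near background limits dim genes. With only the 2 groups compared in limma, values were opposite, higher in mannitol 20, osmotic list protoplast v intact 0.0664. With array weights in limma, values were osmotic v intact higher 1189, osmotic v intact lower 1193, osmotic v intact higher 2-fold 548, shared rises 777, shared falls 974, opposite, higher in mannitol 99, opposite, lower in mannitol 44. With quantile normalization in limma, values were opposite, lower in mannitol 16, osmotic list protoplast v intact 0.0592. With median centring in limma, values were protoplast v osmotic lower 2-fold 1363, set apart lower 1141, osmotic list protoplast v intact 0.0761, replication list protoplast v osmotic 0.0788. With hybridisation control centring in limma, values were osmotic v intact lower 334, opposite, higher in mannitol 8, opposite, lower in mannitol 0. With dimmest 40 percent left out in limma, values were osmotic v intact lower 770, shared falls 669, opposite, higher in mannitol 33, opposite, lower in mannitol 15, replication list protoplast v osmotic 0.0961. With every probe set, 22746 tests in place of 13356, counts were osmotic v intact higher 944, osmotic v intact lower 892, osmotic v intact higher 2-fold 661, osmotic v intact lower 2-fold 483, protoplast v intact higher 3956, protoplast v intact lower 6954, protoplast v intact higher 2-fold 2979, protoplast v intact lower 2-fold 4897, protoplast v osmotic higher 3366, protoplast v osmotic lower 6199, protoplast v osmotic higher 2-fold 2447, protoplast v osmotic lower 2-fold 3936, shared rises 756, shared falls 765, shared 2-fold rises 529, shared 2-fold falls 409, set apart higher 2165, set apart lower 3387, opposite, higher in mannitol 34, opposite, lower in mannitol 20. With pseudocount 1 in limma, values were osmotic v intact higher 300, osmotic v intact lower 214, osmotic v intact lower 2-fold 181, shared falls 190, shared 2-fold falls 154, opposite, higher in mannitol 4, opposite, lower in mannitol 2, correlation of fold changes 0.589, osmotic list protoplast v intact 0.058, WRKY list protoplast v intact 0.0567. With pseudocount 64 in limma, values were osmotic v intact lower 821, shared falls 734, opposite, higher in mannitol 35, opposite, lower in mannitol 12, WRKY list protoplast v intact 0.0616. With replicates 1 and 2 of each group in limma, values were osmotic v intact higher 839, osmotic v intact higher 2-fold 546, shared rises 629, opposite, higher in mannitol 62, opposite, lower in mannitol 29, peroxidase list protoplast v intact 0.0472, osmotic list protoplast v intact 0.121, replication list protoplast v osmotic 0.0731. With batch term for the third arrays in limma, values were osmotic v intact higher 761, osmotic v intact lower 845, shared rises 594, shared falls 715, opposite, higher in mannitol 34, opposite, lower in mannitol 21, osmotic list protoplast v intact 0.0751, WRKY list protoplast v intact 0.0771. At the stricter adjusted p under 0.01, counts were osmotic v intact higher 167, osmotic v intact lower 119, osmotic v intact higher 2-fold 163, osmotic v intact lower 2-fold 112, shared rises 152, shared falls 111, shared 2-fold rises 146, shared 2-fold falls 103, opposite, higher in mannitol 1, opposite, lower in mannitol 0. With an estimated correlation in limma camera, list tests lost were replication list osmotic v intact 0.136, osmotic list osmotic v intact 0.136, immunity list osmotic v intact 0.174, GSTU list osmotic v intact 0.136, WRKY list osmotic v intact 0.246, replication list protoplast v intact 0.153, osmotic list protoplast v intact 0.153, immunity list protoplast v intact 0.153, photosynthesis list protoplast v intact 0.153, GSTU list protoplast v intact 0.153, WRKY list protoplast v intact 0.344, XTH list protoplast v intact 0.129, replication list protoplast v osmotic 0.233, immunity list protoplast v osmotic 0.233, photosynthesis list protoplast v osmotic 0.233, so that only the XTH list protoplast v osmotic stayed, at 0.0488. With fry in limma, which tests a list against no change where camera tests it against other genes, lists under the threshold in fry and not in camera were XTH list osmotic v intact 0.0403, peroxidase list protoplast v intact 4.3e-04, expansin list protoplast v intact 0.0119, peroxidase list protoplast v osmotic 0.00181, expansin list protoplast v osmotic 0.00735, osmotic list protoplast v osmotic 0.0149, GSTU list protoplast v osmotic 0.00322.

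With 1 array left out, in limma, ranges were osmotic v intact higher 202 to 622, osmotic v intact lower 158 to 708, osmotic v intact lower 2-fold 147 to 321, shared rises 178 to 447, shared falls 145 to 576, shared 2-fold falls 131 to 248, opposite, higher in mannitol 2 to 49, opposite, lower in mannitol 1 to 24, osmotic v intact higher 2-fold 195 to 422, shared 2-fold rises 167 to 341, correlation of fold changes 0.569 to 0.639, osmotic list protoplast v intact 0.0285 to 0.0893, WRKY list protoplast v intact 0.0221 to 0.113, replication list protoplast v osmotic 0.0184 to 0.0551, GSTU list protoplast v osmotic 0.0197 to 0.245.

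With the replicate number as a block in limma, values were opposite, higher in mannitol 21, osmotic list protoplast v intact 0.0763, WRKY list protoplast v intact 0.0763, and 556 higher and 566 lower genes were called in osmotic v intact. It changed no other list test and moved no other count by over 1.5 times, while 11 calls of single genes from the lists or named in the text were lost, 15 were gained and 422 were made in both fits. Same-numbered arrays had correlations of deviations from 0.0217 to 0.323, with all 3 pairs over 0.1 in osmotic v intact (0.101 to 0.310) and protoplast v osmotic (0.122 to 0.323) but not in protoplast v intact. Different numbers reached 0.152, and 6 of 9 arrays correlated best with their own number, so the numbers were not taken to pair the samples.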

Other observations

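Of the tests below, those on the 47 added lists were chosen after the annotation was seen, and none of their calls held with an estimated correlation. Of 7 calmodulin-like genes, which encode calcium sensors, 1 rose in mannitol, CML30 by 1.24 ± 0.15 (limma's camera adjusted p = 0.0287, and adjusted p = 0.361 with an estimated correlation), against 2 with quantile normalization and with median centring, and 5 rose in protoplasts against intact cells (limma's camera adjusted p = 0.0177, and adjusted p = 0.402 with an estimated correlation), CML42 by 5.35 ± 0.31 and CML37 by 5.32 ± 0.20. Against osmotic cells 3 rose (limma's camera adjusted p = 0.0382, and adjusted p = 0.409 with an estimated correlation), and 4 with median centring. All 5 beta-tubulin genes fell in protoplasts against intact cells, TUB7 with -2.82 ± 0.17 and TUB6 with -2.19 ± 0.29 (limma's camera adjusted p = 0.0299, and adjusted p = 0.52 with an estimated correlation), and against osmotic cells (limma's camera adjusted p = 0.0382, and adjusted p = 0.681 with an estimated correlation), where 4 fell with quantile normalization and with median centring. Of 47 glycosyltransferase genes of the UGT family, 13 rose and 3 fell in protoplasts against intact cells (limma's camera adjusted p = 0.0299, and adjusted p = 0.419 with an estimated correlation), with UGT73B4 at 7.49 ± 0.34 and UGT71C3 at -1.41 ± 0.32, against 12 and 3 with quantile normalization, 13 and 2 with median centring and 10 and 3 with hybridisation controls. Of 8 autophagy genes, 3 rose in mannitol, ATG8H by 2.75 ± 0.26 and ATG8E by 2.51 ± 0.23 (limma's camera adjusted p = 2.9e-04, and adjusted p = 0.325 with an estimated correlation).

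Of 8 subtilase genes with SBT symbols, 3 rose in protoplasts against osmotic cells, SBT3.5 by 3.52 ± 0.22 and SBT3.3 by 2.01 ± 0.30 (limma's camera adjusted p = 0.0382, and adjusted p = 0.409 with an estimated correlation), and 4 with quantile normalization and with median centring. The symbol rule left out the subtilisin-like protease gene ARA12, which changed by -3.82 in protoplasts against intact cells. Of 11 PRA1 genes 6 rose, PRA1.B4 by 2.80 ± 0.35 (limma's camera adjusted p = 0.0382, and adjusted p = 0.409 with an estimated correlation), against 7 higher with median centring and 4 higher and 1 lower with hybridisation controls. Of 12 ubiquitin protease genes 4 rose, UBP20 by 0.85 ± 0.18 (limma's camera adjusted p = 0.0479, and adjusted p = 0.64 with an estimated correlation), against 7 with quantile normalization and 8 with median centring, but none was higher and 1 lower with hybridisation controls. In mannitol 3 of 9 PUB genes rose, PUB23 by 2.75 ± 0.40 (limma's camera adjusted p = 0.0357, and adjusted p = 0.361 with an estimated correlation), but 1 with hybridisation controls. There 2 of 8 CHR genes fell, CHR17 with -0.83 ± 0.16 and CHR40 with -0.60 ± 0.16 (limma's camera adjusted p = 0.0287, and adjusted p = 0.361 with an estimated correlation), but none with hybridisation controls. Calls of these families lost without 1 array had a highest limma adjusted p without intact replicate 1 for CHR40 at 0.148, without intact replicate 3 for CHR17 at 0.0621, and without osmotic replicate 2 for PUB22 at 0.15. The symbol families GSTU, WRKY and XTH repeat lists of the report, and the PUB family shares PUB22, PUB23 and PUB24 with the immunity list. The 69 genes of the plastid genome had medians of 0.24 and 0.28 in protoplasts against intact and osmotic cells (limma's camera adjusted p = 0.0299, and adjusted p = 0.747 with an estimated correlation against intact cells, and limma's camera adjusted p = 0.00254, and adjusted p = 0.681 with an estimated correlation against osmotic cells), near 0 with hybridisation controls. Of them, 2 were called higher and 1 lower against intact cells and 3 higher against osmotic cells, but 20 higher in each with median centring. The 16 of the mitochondrial genome were not called as a list in any comparison. Their median was -0.35 in mannitol (limma's camera adjusted p = 0.0963, and adjusted p = 0.682 with an estimated correlation). In protoplasts it was 0.02 against intact cells (limma's camera adjusted p = 0.542, and adjusted p = 0.894 with an estimated correlation) and 0.47 against osmotic cells (limma's camera adjusted p = 0.0611, and adjusted p = 0.681 with an estimated correlation).

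A hypothesis written before its result was that wall digestion moves the mannitol response further the same way. Of 980 genes called in mannitol, 72.6%, 70.7% and 74.6% lay further from intact cells than osmotic cells did on the 3 protoplast arrays, the lowest being 70.7%, and 262 rises and 258 falls were called further against 76 and 51 back. These counts depended on the scaling: with hybridisation controls 167 and 215 were called further against 67 and 19 back, and with median centring 271 and 195 against 57 and 72. The lowest shares of rises and falls further the same way were 61.1%, with hybridisation controls, and 66.1%, with median centring. Sharing the osmotic arrays works against this pattern. The longer total time of protoplasts in mannitol may give it too and was not tested.

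Splits of the 6 arrays of each comparison into 3 and 3, the real one included, number 10, too few for a share under 0.05. The real split called 980, 6010 and 5207 genes in the 3 comparisons (limma adjusted p under 0.05), and the highest of the others called 0 in each. Every other split mixed both groups, so their difference entered the spread, and the 0 calls cannot serve as a measure of chance.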
